A study of Mus musculus with 3 samples.

How the data were processed

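RNA was measured in 3 samples of mouse CD8+ T cells from spleen and lymph node, 1 in each of the groups young TCR, young TRM and aged TRM. Per the labels, RNA was extracted with a column kit, standard Illumina libraries were made from total RNA and sequenced on a HiSeq instrument, and the submitters' notes name Bowtie, without a version, and the mouse assembly GRCm38 (mm10). The program that counted reads and the gene annotation are not given in the sources used here, nor is the treatment of reads that fit more than 1 gene.

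The deposited table gave, for each gene and numbered column, an estimated count of reads (a value that need not be whole) and a TPM value. The file headers call the former read counts, and they were taken as estimated counts because they are not always whole. These counts were used for all main results. The deposited TPM, which divides by transcript length, was used as an alternative unit. Each sample had 2 numbered columns. The labels describe 1 sample per group and do not say what the numbers stand for, so the columns were treated as repeat measurements of 1 sample and not as replicates. If they were separate cultures or animals, the spread between them would be biological. A further 24 value columns of comparisons made by the authors were not used here. Of the gene IDs, 17071 were found in the reference table of assembly GRCm38.p6, from which positions were taken, and 23 symbols that had been turned into dates were restored from the gene ID.

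The columns of a sample were rounded and summed, giving 39915663, 36021887 and 40385477 reads with 16022, 15729 and 16115 genes above 0. The columns held between 16084688 and 20245040 reads. For genes of at least 50 reads, the variance between the columns of a sample was 3.04, 2.97 and 2.31 times the counting variance, and the median gene differed by 1.05-fold. Set against each other by the calling rule, the columns of young TCR gave 10 higher and 11 lower genes, those of young TRM 10 and 11, and those of aged TRM 8 and 12. Ribosomal protein genes held 8.43%, 8.33% and 7.43% of reads, and the 10 genes with most reads 4.99%, 4.77% and 4.65%. No mitochondrially encoded gene was listed.

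Libraries were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3 (1.02, 0.978 and 1.01), and log2 ratios of CPM with a pseudocount of 1 were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A gene was tested if it reached 1 CPM in at least 1 of the libraries compared. It was called if its log2 ratio was at least 1 in size and the 95% Clopper-Pearson interval of the ratio, from the split of the reads between the libraries, excluded 1. No p-value was computed, since with 1 library per group the variation between mice cannot be estimated. Reads are not independent molecules, so these intervals cover counting error only. The rule was tested on simulated data with counting error plus the extra spread seen between the columns of a sample (SD 2.99%). There it called 49 of 50 genes raised 3-fold, 45 of 50 lowered 3-fold, 0 of 50 raised and 0 of 50 lowered 1.5-fold, and 0 of 11280 unchanged genes. The extra spread was estimated from genes with many reads only and applied to all genes, so weakly expressed genes may vary more than was simulated. Columns of the same sample did give calls, such as 10 higher and 11 lower genes in young TCR. The 0 of 11280 is thus not the rate of false calls in the data.

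Young TRM was compared with young TCR, and aged TRM with young TRM. Aged TRM against young TCR was given as values, since age and cytokines both differ there. The comparisons, the calling rule, 35 gene lists and the rule for named genes were set before the data were examined. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on expression in 20 bins, if at least 3 members were tested. The percentile describes these libraries and is no test across mice. Random lists draw each gene singly, whereas members of a list may vary together, so a small shared shift can place a list outside the limits. In the first comparison 11 lists lay above and 8 below, and in the age comparison 14 above and 6 below. Of 710 list entries, 32 were not listed in the table, Zfp683 among them. Genes were named if they were among the 10 called genes with the highest or the lowest log2 ratio and at least 10 CPM, among up to 4 members of each list with the largest ratios, or on a list of genes fixed in advance, which included Itgae, Cd69, Itga1, Zfp683, Cxcr6, S1pr1, Klf2, Tcf7, Cd8a, Ifng, Gzmb, Il15ra, Tgfbr1, Tgfbr2 and Il2rb. Not every gene that the rule takes is reported here. Predicted genes, pseudogenes and receptor segments were left out of the first part. Cd4 in both comparisons, and in the first comparison Prdm1, Tgfb3, Socs1, Ctsw, Ccr2, Ccr4, Cxcr5, Trp53inp1, Gzmm, Crtam, Slfn5, Zbtb7b and Tyrobp, were named after their values were seen, mostly to complete counts of 5 or fewer.

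Alternatives tried were scaling by totals only or by DESeq2 1.42.0 size factors, pseudocounts of 0.25 and 5, the authors' TPM, no filter or a filter of 10 CPM, fold thresholds of 1.5 and 4, no interval or an interval wholly beyond 2-fold, equal depth by thinning, and selection on 1 random part of the reads with measurement on the rest. Column 1 alone, column 2 alone, all 4 pairings of the columns, and selection on 1 column with measurement on the other were added after seeing the data. Figures were drawn with matplotlib 3.10.9.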

Results

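RNA was sequenced from CD8+ T cells, the cytotoxic T cells of the immune system, taken from mouse spleen and lymph node and studied on day 3 of culture. The 3 samples formed 3 groups of 1 sample each. The young TCR sample came from mice of 6 weeks and received antibodies against CD3 and CD28 at 1 µg/ml. These act on the T cell receptor (TCR) and on a co-stimulatory receptor. The young TRM sample, from mice of the same age, also received IL-15 at 20 ng/ml and TGF-beta at 5 ng/ml, cytokines that favour tissue-resident memory T cells (TRM). The aged TRM sample had the TRM condition and came from mice of 18 months. An aged sample with receptor stimulation alone was not analysed here. The gene table gave 39915663 reads to young TCR, 36021887 to young TRM and 40385477 to aged TRM. Each sample had 2 numbered columns, whose meaning the labels do not give, and these were treated as repeat measurements of 1 sample. On that reading there were no biological replicates, so no difference between groups was tested against variation between mice or cultures. Levels are given in CPM, the reads of a gene scaled to a common library size by the trimmed-mean (TMM) method. Intervals are 95% counting intervals that cover counting error only, except where a bootstrap is named. A gene is said to have risen or fallen where its CPM, with a pseudocount of 1 added, differed by at least 2-fold and the interval of its ratio excluded 1. Log2 ratios hold this pseudocount and printed folds do not, so a weakly expressed gene may differ by over 2-fold without being called. Gene lists were chosen before the data were examined, and a list is said to lie above or below matched genes where its median log2 ratio lay in the highest or the lowest 2.5% of random lists of like expression.

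The first comparison asked how IL-15 and TGF-beta altered stimulated young CD8+ T cells. Transcripts of tissue residency, of the TGF-beta response and of the interferon response were higher in young TRM than in young TCR, and transcripts of cytotoxic granules were lower. Itgae, which encodes the CD103 chain of the integrin that binds E-cadherin, rose from 8.98 to 605 CPM (67.4-fold, interval 60.8 to 75.0). Cdh1, which encodes E-cadherin itself, rose from 1.16 to 80.8 CPM (69.7-fold, 52.3 to 95). Gzmb, which encodes the protease granzyme B, fell from 4393 to 1251 CPM (a log2 ratio of -1.81), and Prf1, which encodes the pore-forming protein perforin, fell from 157 to 34.1 CPM. Of 11588 genes tested, 484 rose and 417 fell, together 7.78%. Beyond 2-fold in all 4 pairings of the deposited columns were 399 higher and 323 lower genes.

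Of 23 tested tissue residency genes, 12 rose and 1 (Prdm1) fell, and the list's median log2 ratio of 1.04 lay above matched genes. Besides Itgae and Cdh1, Ldlrad4, a brake on TGF-beta signalling, rose from 11 to 273 CPM, and Ahr, the aryl hydrocarbon receptor, rose from 2.17 to 47.2 CPM. Itga1, which encodes the CD49a integrin chain, rose from 0.222 to 4.54 CPM. Cd69, an early activation marker that holds cells in tissue, had 102 and 186 CPM (log2 ratio 0.86), and the chemokine receptor gene Cxcr6 had 47.9 and 47.2 CPM. Among 15 TGF-beta response genes 10 rose and 2 fell, Tgfb3 among them, with a median of 1.73, the highest of all the lists. The feedback inhibitors Pmepa1 and Skil rose from 12.5 to 142 CPM and from 52.0 to 346 CPM. The receptor genes Tgfbr1 and Tgfbr2 rose by log2 ratios of 1.89 and 1.02, the latter no longer past 2-fold when libraries were scaled by totals only (0.96), with column 1 alone (0.93) and, narrowly, with 2 other settings. Of 6 type 17 genes 3 rose, namely Ahr, Ccr6 and Maf, and the median of 1.04 lay above matched genes (0.62 with a pseudocount of 5 and 0.64 with the authors' TPM). Markers of NK and innate lymphoid cells moved the same way as these lists, with a median of 1.01.

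The 18 egress and recirculation genes also lay above matched genes, with a median of 0.30 (0.19 with a pseudocount of 5). Klf2, a transcription factor that maintains circulation of T cells, rose from 35.0 to 151 CPM, and Cx3cr1 and Sidt1 rose as well, while Eomes fell from 217 to 93.5 CPM. The egress receptor gene S1pr1 had 51.4 and 50.2 CPM. The 15 naive and stem-like memory genes lay inside the matched range at 0.02, with 2 risen (Igfbp4 and Id3) and 2 fallen (Slamf6 and Satb1). Tcf7, a transcription factor of naive and memory T cells, had 653 and 476 CPM. Chemokine receptor and integrin genes lay inside at -0.07. In that list 5 of 26 rose (Itgae, Cx3cr1, Ccr8, Itga1 and Ccr6) and 5 fell, among them Ccr2, Ccr4, Cxcr5 and Itgb3, the last at 263 and 31.9 CPM.

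Interferon response genes lay above matched genes with a median of 0.99, and 17 of 37 rose while 1 (Slfn5) fell. Isg20 rose from 3.58 to 91.9 CPM, Ifit3 from 4.81 to 87.7 CPM, and Iigp1, a GTPase induced by interferon, from 134 to 693 CPM. Ifit3b, a close relative of Ifit3, rose from 0.789 to 22.7 CPM. NK receptor genes followed with a median of 0.92, where 9 of 24 rose and 1 (Crtam) fell. Most members were weakly expressed, and the median was 0.33 with a pseudocount of 5 and 0.43 over the 9 genes of at least 10 CPM. Klri2 rose from 2.17 to 14.7 CPM and Klra5 from 0.493 to 4.03 CPM, and Ncr1, an activating receptor of NK cells, from 0.0493 to 2.19 CPM, which in young TCR was near the limit of counting. The list shares members with the NK and innate lymphoid markers, whose median was 1.01 (0.35 with a pseudocount of 5). Immediate response genes of the T cell receptor lay above matched genes at 0.36. Of these, 8 of 25 rose, among them Jun (61.4 to 335 CPM), Irf8 (278 to 939 CPM) and Fosb (2.0 to 7.38 CPM), and 1 fell, Batf (62.7 to 11.2 CPM). Virtual memory genes, which mark memory-like cells that have met no antigen, had a median of 0.25, above matched genes. Of 19 members 4 rose (Ly6c1, Klrc1, Itgae and Bcl2) and 3 fell (Eomes, Ccl5 and Gzmm).

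**Figure D1:**
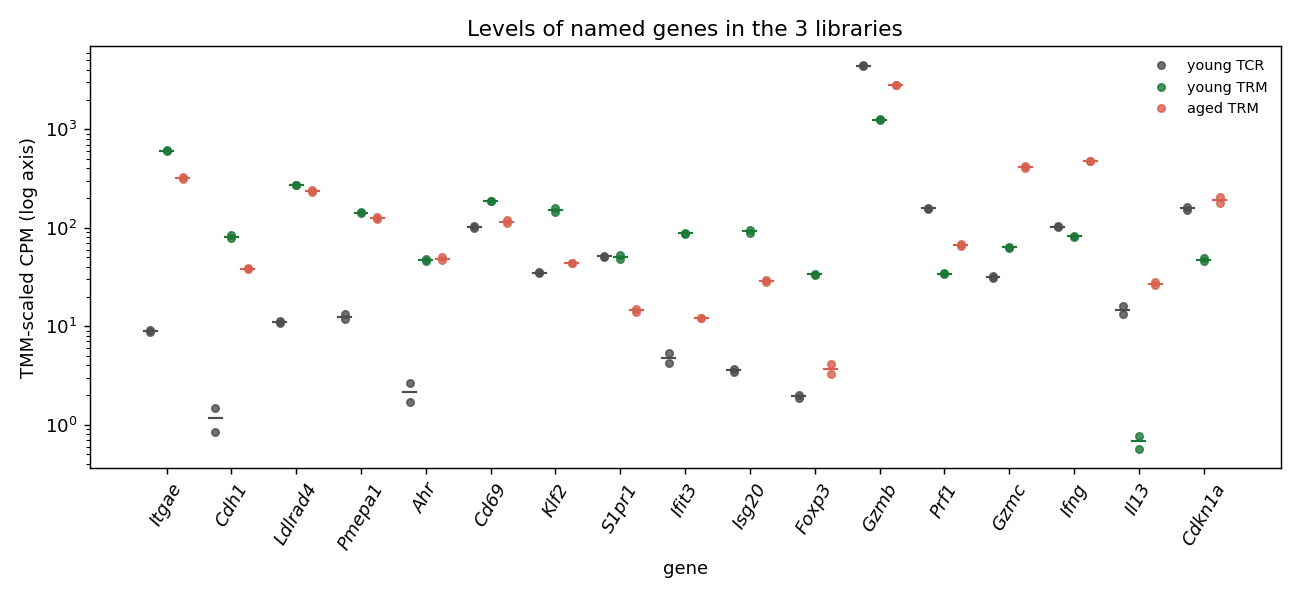
Levels of named genes in the young TCR, young TRM and aged TRM libraries, in TMM-scaled CPM on a log axis, with genes along the horizontal axis. Each point is 1 deposited column of a library and each short line is the library with its columns summed, such as Itgae at 8.98, 605 and 320 CPM and Ifng at 103, 82.1 and 478 CPM.

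Cytotoxic granule genes lay below matched genes with a median of -0.74. Of 17 tested, 7 fell and 1 (Ctsw) rose. Apart from Gzmb and Prf1, the protease inhibitor genes Serpinb6b and Serpinb9 fell from 462 to 43.2 CPM and from 327 to 54.5 CPM, and Cst7 fell from 138 to 36.1 CPM. The 22 age-associated CD8 T cell genes lay below matched genes at -0.42, with 6 fallen, among them the chemokine gene Ccl5 (32.3 to 4.74 CPM), Il10 (3.75 to 0.965 CPM) and Penk (81.2 to 33.2 CPM). Some members, Ccl5 and Il10 among them, are also in the secreted cytokine list, and others such as Cst7 are in the granule list. Secreted cytokine and chemokine genes went both ways and lay inside at 0.16, with 6 of 20 risen and 7 fallen, though above matched genes with genes of at least 10 CPM (0.53). Il13 fell from 14.8 to 0.681 CPM and Il24 from 9.27 to 0.397 CPM, while Ccl1 rose from 6.31 to 55.9 CPM. Ifng, which encodes interferon gamma, had 103 and 82.1 CPM. Inhibitory receptor and exhaustion genes lay inside at -0.05. The ectoenzyme genes Nt5e and Entpd1 rose from 40.5 to 292 CPM and from 12.1 to 69.7 CPM, and Havcr2, which encodes the inhibitory receptor TIM-3, fell from 61.8 to 8.03 CPM, as did Batf. B and plasma cell markers moved the same way as the granule and age-associated lists, with a median of -1.09.

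The 24 glycolysis genes had a median of -0.27, below matched genes, with 1 fallen, the glucose transporter gene Slc2a3 (695 to 247 CPM). Heat shock and unfolded protein response genes lay below at -0.21. In that list Hspd1, a mitochondrial chaperone, fell from 994 to 484 CPM and Hspa1b fell from 4.0 to 1.14 CPM, while 20 of 22 passed no threshold. Oxidative phosphorylation genes lay below at -0.15, with 29 of 30 members under 0 and 1 fallen, Ndufa4 (108 to 43.7 CPM). Fatty acid uptake and oxidation genes lay below at -0.17, with 1 fallen, Plin2 (59.0 to 18.7 CPM). Both of these lists moved inside the matched range with the authors' TPM (-0.16 and -0.17), the fatty acid list also with column 1 alone (-0.16). Integrated stress response genes lay above at 0.24, with Nupr1, Chac1, Trib3 and Cebpb risen, though inside with column 1 alone (0.19). B and plasma cell markers moved the same way as the lower lists and NK markers the same way as the higher one, with medians of -1.09 and 1.01.

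The other lists lay mostly inside the matched range. Of 31 cell cycle genes 1 rose, Cdk6 (223 to 550 CPM), and the median was -0.01. Senescence and cell cycle inhibitor genes had a median of -0.05. In that list Cxcl10, Il1a and Trp53inp1 rose, while 2 genes fell, among them Cdkn1a from 157 to 47.2 CPM. Apoptosis regulators had a median of -0.08, with Bcl2 and Bmf risen and Casp1 and Casp4 fallen, and lay below with column 2 alone (-0.14). Genes of the STAT5 and gamma-chain cytokine response had a median of 0.11, with Socs1, Socs2, Bcl2 and Osm risen and Id2 fallen. The survival gene Bcl2 rose from 308 to 788 CPM. Il2rb, the receptor chain shared by IL-2 and IL-15, had 1372 and 1245 CPM, and Il15ra had 20.0 and 20.2 CPM. Cholesterol synthesis genes lay at -0.11 and one-carbon and serine metabolism genes at -0.04, with no member past the threshold in either. The cholesterol list lay below matched genes with column 1 alone (-0.15) or column 2 alone (-0.16). T cell identity genes lay above at 0.23, with 1 risen, Cd8a (747 to 1822 CPM).

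Among markers of other cells, the 13 B and plasma cell genes lay below matched genes at -1.09, with 8 fallen, from levels such as 7.40 CPM for Ms4a1 and 6.07 CPM for Cd22 in young TCR. The NK and innate lymphoid genes lay above at 1.01, with 5 of 10 risen (Ncr1, Klrb1c, Kit, Fcer1g and Tyrobp), of which Kit rose from 29.6 to 78.4 CPM. Red cell and platelet genes lay below at -1.20 over 3 members, with Ppbp and Pf4 fallen and Hbb-bt risen, and inside with the authors' TPM (-0.27), with a median of -0.46 at a pseudocount of 5. The CD4 T cell list lay inside at -0.10. Foxp3, the transcription factor of regulatory T cells, rose from 1.95 to 33.6 CPM and Ikzf2 rose from 117 to 315 CPM, while Trat1, Gata3 and Zbtb7b fell and Cd4 itself, chosen after its values were seen, had 10.5 and 12.4 CPM. Myeloid markers lay inside at -0.15, with Mpeg1 and Ctss risen and Itgax fallen, though above with the 3 genes of at least 10 CPM (1.30), and stromal and endothelial markers lay inside at -0.09. Only 2 gamma-delta T cell genes were tested, too few for a median, and no mitochondrially encoded gene was listed in the table. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty lay inside at 0.03, with Ddx3y at 116 and 121 CPM.

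The 10 genes that rose most, among those of at least 10 CPM in the higher library, were Itgae, Lcn10, Gja5, Cdh1, Car2, Cx3cr1, Igfbp4, Drc1, Tnfrsf11a and Cpd. Itgae (gene ID 16407) lies on chromosome 11, positions 73090505 to 73147449 of GRCm38.p6. Gja5, a gap junction gene, had 1 read in young TCR and 1355 in young TRM. Cx3cr1, which encodes the receptor for fractalkine, rose 154-fold (83.3 to 321) from 10 reads in young TCR. The 10 that fell most were Epas1, Tnfrsf8, Adam8, Serpinb9b, Tg, Pou2af1, Serpinb6b, Il13, Podnl1 and Kremen2. Epas1 (gene ID 13819), which encodes the hypoxia-inducible factor HIF-2alpha, fell from 105 to 1.31 CPM and was 80.3-fold lower (60.1 to 110). It lies on chromosome 17, positions 86753864 to 86833410. Tnfrsf8, which encodes the activation receptor CD30, fell from 77.6 to 1.36 CPM. Across genes the log2 levels of both libraries had a Pearson r of 0.959, where genes are not independent replicates. Calls of Hspa1b, Fcer1g, Pax5, Itgax and Hbb-bt were lost under at least 1 of totals-only scaling, the authors' TPM and either column alone. A pseudocount of 5, which shrinks the ratios of weakly expressed genes, also ended these calls and those of Itga1, Tgfb3, Ccr6, Maf, Klra5, Klrb1c, Ncr1, Tyrobp, Fosb, Il10, Il1a, Gzmm, Slfn5, Cebpb, Bmf, Casp4, Zbtb7b, Cd22 and Pf4.

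The age comparison set aged TRM against young TRM, both with the added cytokines. Cytotoxic granule genes and secreted cytokine and chemokine genes were higher in the aged library, and interferon response and egress genes were lower. Ifng rose from 82.1 to 478 CPM (5.82-fold, 5.59 to 6.05), and Gzmc, a granzyme gene, rose from 63.5 to 413 CPM (6.5-fold, 6.22 to 6.80). Ifit3, induced by interferon, fell from 87.7 to 12.1 CPM (7.28-fold lower, 6.61 to 8.02). S1pr1 fell from 50.2 to 14.5 CPM. Of 11575 genes tested 260 rose and 133 fell, together 3.40%, against 7.78% in the first comparison, and 184 and 95 passed 2-fold in all 4 pairings of the columns.

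Of 20 cytotoxic granule genes 12 rose and 0 fell, with a median of 1.2. Gzmb rose from 1251 to 2807 CPM, below its level of 4393 CPM in young TCR. The clustered granzyme genes Gzmd, Gzme and Gzmf rose from 1.19 to 32.2 CPM, from 0.426 to 11.4 CPM and from 0.227 to 7.06 CPM. These genes resemble each other in sequence, and how reads that fit several of them were counted is not given in the sources used here. Secreted cytokine and chemokine genes had a median of 1.34, with 15 of 25 risen and 0 fallen. That median was the highest in this comparison, but not with a pseudocount of 5 (0.57, against 1.05 for granule genes) or with genes of at least 10 CPM (1.13, against 1.2). Besides Ifng, Il13 rose from 0.681 to 27.0 CPM (39.7-fold, 26.5 to 62.2), Il24 from 0.397 to 15.7 CPM and Il9 from 0.341 to 5.61 CPM. The aged columns were far apart for Il24 (9.91 and 21.4 CPM) and Il9 (2.71 and 8.49 CPM). Age-associated CD8 T cell genes lay above at 0.74, with 8 of 22 risen, among them Penk (33.2 to 228 CPM), Ccl3 (30.6 to 131 CPM), Il10 (0.965 to 6.86 CPM) and Ccl5 (4.74 to 15.0 CPM). The list shares Ccl3, Ccl4, Ccl5 and Il10 with the cytokine list and Gzmk, Nkg7, Cst7 and Ctla2a with the granule list. Its median is thus not a separate result. B and plasma cell markers moved the same way as these lists with a median of 0.69, while NK and innate lymphoid markers lay inside at 0.12.

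Type 17 genes lay above matched genes at 0.79 (0.42 with a pseudocount of 5 and 0.46 over the 3 genes of at least 10 CPM). Il22, Il21 and Il17a, which are also in the secreted cytokine list, rose to 2.66, 2.58 and 2.41 CPM, with aged columns of 0.436 and 4.86 CPM for Il22. Ccr6 fell from 3.75 to 1.35 CPM. NK receptor genes lay above at 0.44, with 5 of 24 risen (Klra3, Klrc1, Klre1, Klra1 and Cd160). The median was 0.34 with a pseudocount of 5 and 0.96 over the 10 genes of at least 10 CPM. Klrc1, which encodes the receptor chain NKG2A, rose from 117 to 249 CPM. B and plasma cell markers had a median of 0.69 here too. Inhibitory receptor and exhaustion genes lay just inside the upper limit at 0.13, and above it with totals-only scaling (0.17), a pseudocount of 5 (0.12), genes of at least 10 CPM (0.14) or column 2 alone (0.16). In that list Havcr2 rose from 8.03 to 34.3 CPM and Batf and Cd160 rose as well, while Lag3 had 118 and 233 CPM (log2 ratio 0.98). Virtual memory genes lay inside at -0.06, with 2 genes risen (Ccl5 and Klrc1) and 3 fallen, among them Ly6c1 and Ly6c2.

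Interferon response genes lay below matched genes at -0.84, with 14 of 37 fallen, 0 risen and 36 below 0. Rtp4 fell from 11.8 to 1.5 CPM, Ifit3b from 22.7 to 3.64 CPM and Oas3, an antiviral enzyme gene, from 37.2 to 10.6 CPM. Egress and recirculation genes lay below at -0.66, and 7 of 18 fell while 0 rose. Klf2 fell from 151 to 43.8 CPM and Cx3cr1 from 37.9 to 9.99 CPM, beside S1pr1. Naive and stem-like memory genes lay below at -0.25, with 3 of 15 fallen, among them Igfbp4 and Id3, while Tcf7 had 476 and 355 CPM and Il7r 109 and 203 CPM. CD4 T cell markers moved the same way as these lists with a median of -0.30, though the list lay inside when genes under 10 CPM were left out (-0.19). In it Foxp3 fell from 33.6 to 3.71 CPM, and Cd4 had 12.4 and 11.6 CPM.

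Tissue residency genes lay inside the matched range at -0.04, with Rgs2 and Prdm1 risen and Cdh1 fallen among 23. Itgae had 605 and 320 CPM (log2 ratio -0.92), Itga1 4.54 and 6.54 CPM, Cd69 186 and 115 CPM and Cxcr6 47.2 and 74.7 CPM, none past the rule. TGF-beta response genes lay below matched genes at -0.19, with Tgfb3 risen, and inside with the authors' TPM (-0.05) or with column 2 alone (-0.17). Tgfbr1 had 158 and 90.4 CPM and Tgfbr2 240 and 183 CPM. Genes of the STAT5 and gamma-chain cytokine response lay below at -0.19, with 1 fallen, Osm (79.6 to 35.7 CPM), and CD4 T cell markers at -0.30. Il2rb had 1245 and 1119 CPM and Il15ra 20.2 and 15.4 CPM.

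**Figure D2:**
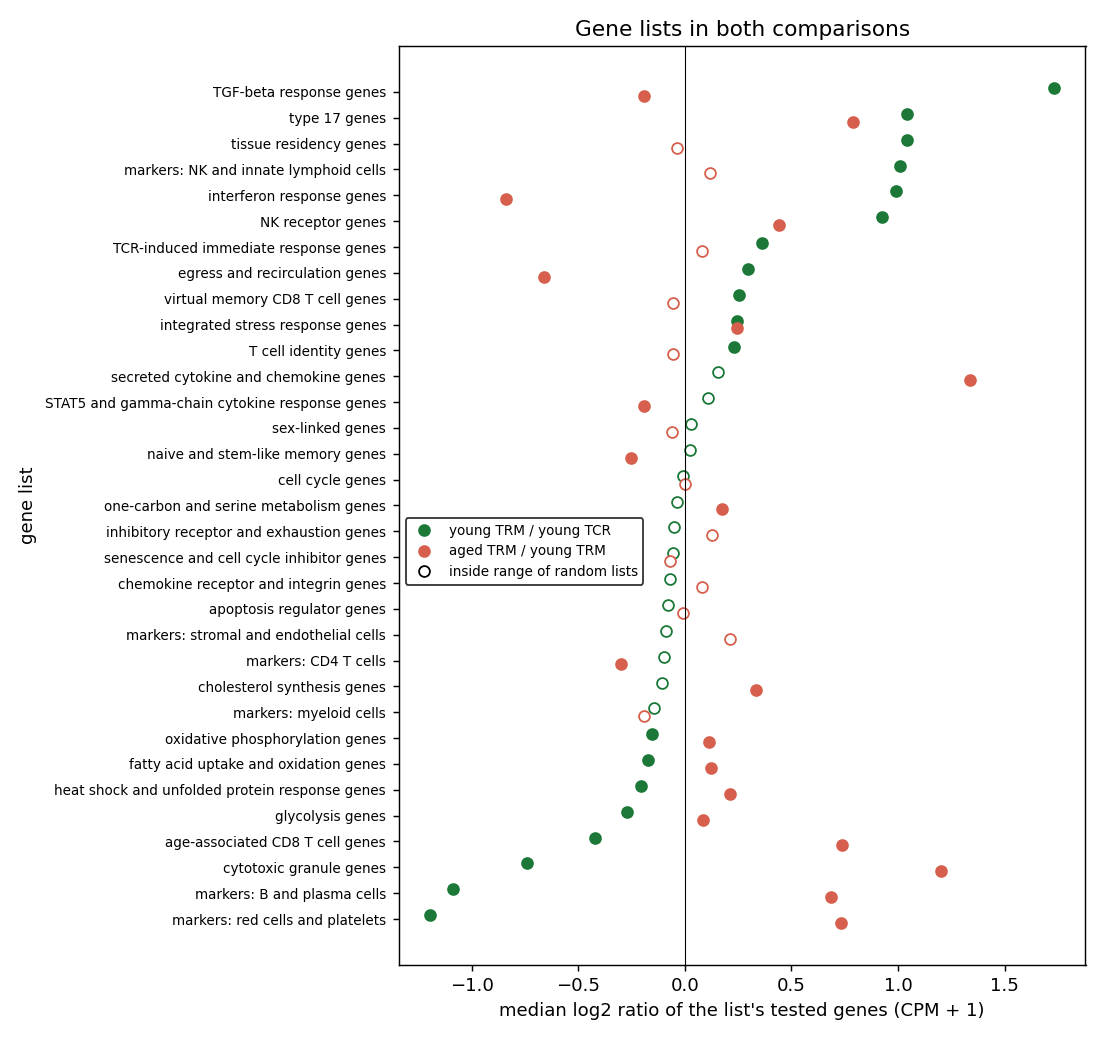
Median log2 ratio of each gene list, in young TRM over young TCR and in aged TRM over young TRM, with the lists on the vertical axis, the log2 ratio on the horizontal axis and open points for lists inside the matched range. Interferon response genes sit at 0.99 and -0.84, cytotoxic granule genes at -0.74 and 1.2, and tissue residency genes at 1.04 and -0.04.

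Metabolic and stress lists shifted by less than 2-fold. The 23 cholesterol synthesis genes all had log2 ratios above 0, with a median of 0.34 above matched genes and no member past the rule. Hsd17b7 had 26.5 and 40.1 CPM, Msmo1 82.8 and 123 CPM and Cyp51 286 and 423 CPM. One-carbon and serine metabolism genes lay above at 0.17, with Aldh1l2 risen from 10.4 to 25.0 CPM. Integrated stress response genes lay above at 0.25 (0.13 with genes of at least 10 CPM), with Stc2, Cth and Atf3 risen, the last, a stress-induced transcription factor, from 12.5 to 31.9 CPM. Heat shock and unfolded protein response genes lay above at 0.21 with none risen. Glycolysis genes lay above at 0.08, oxidative phosphorylation genes at 0.11 and fatty acid genes at 0.12, with Cd36 risen from 0.426 to 3.91 CPM (aged columns 2.52 and 5.30 CPM). Each of these 3 lists moved inside under another setting. Glycolysis did so with the authors' TPM (0.13) and with column 2 alone (0.02), oxidative phosphorylation with column 1 alone (0.07), and fatty acid genes with TPM (0.16), with genes of at least 10 CPM (0.08) and with column 1 alone (0.05). B and plasma cell markers, with a median of 0.69, moved the same way as these lists.

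Cell cycle genes lay inside at 0.00 with 0 of 31 past the rule. Senescence and cell cycle inhibitor genes lay inside at -0.07, but above matched genes with the authors' TPM (0.27) and below with genes of at least 10 CPM (-0.22), so the list had no stable side. It had Cdkn1a, which encodes the cell cycle inhibitor p21, risen from 47.2 to 192 CPM and Il1a risen from 3.18 to 33.6 CPM. Apoptosis regulators lay at -0.01, with Casp1 and Casp4 risen from 5.88 to 20.4 CPM and from 6.16 to 20.0 CPM. T cell receptor immediate response genes lay at 0.08, with Batf risen and Fosb fallen, and above matched genes with genes of at least 10 CPM (0.17) or column 2 alone (0.11). Chemokine receptor and integrin genes also lay at 0.08, with Ccr4 risen and Cx3cr1 and Ccr6 fallen. T cell identity genes lay at -0.06 with none past the rule, and Cd8a had 1822 and 1632 CPM.

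B and plasma cell markers lay above matched genes at 0.69 (0.36 with a pseudocount of 5), with 4 of 12 risen, among them Pax5, Ms4a1 and H2-Eb1, the last from 5.88 to 13.8 CPM. In NK and innate lymphoid markers 0 of 10 passed the rule, and Ncr1 had 2.19 and 1.18 CPM. Myeloid markers lay inside at -0.19 and stromal and endothelial markers at 0.21. Red cell and platelet genes lay above at 0.73 over 4 members, with Hbb-bt risen from 2.5 to 6.15 CPM. Of the other settings only the authors' TPM (1.04) kept that placement, and the list lay inside with scaling by totals only or by DESeq2, with either pseudocount (1.12 with 0.25 and 0.23 with 5) and with either column alone. For gamma-delta T cells 1 gene was tested. The Y-linked genes had a median of -0.06 and lay inside.

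In the aged library the 10 genes that rose most were Il13, Gzmd, Il24, Serpinb9b, Gzme, Serpine2, Il1a, Tnfrsf8, Penk and Gzmc. Il13 (gene ID 16163) lies on chromosome 11, positions 53631323 to 53634702 of GRCm38.p6, and Gzmc, Gzmd and Gzme lie on chromosome 14, with Gzmc at 56231397 to 56241647. Serpine2, a protease inhibitor gene, rose from 15.8 to 144 CPM (9.12-fold, 8.36 to 9.97). The 10 that fell most were Trim30c, Foxp3, Ly6c1, Ifit3, Drc1, Tnfrsf11a, Ifi213, Rtp4, Ifit3b and Ifi208. Foxp3 (gene ID 20371) lies on chromosome X, positions 7579676 to 7595243, and was 9.04-fold lower (7.63 to 10.8). Tnfrsf11a, which encodes the receptor RANK, fell from 36.5 to 5.09 CPM. Calls of Rgs2, Cdh1, Prdm1, Ccr6, Cd160, Klre1, Klra1, H2-Eb1, Il22, Hbb-bt, Pax5 and Ms4a1 were lost under at least 1 of totals-only scaling, the authors' TPM and either column alone. A pseudocount of 5 also ended these calls and those of Il9, Il10, Il21, Il17a, Cd36, Aldh1l2, Batf, Fosb, Id3, Tgfb3 and Klra3.

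The genes called in young TRM against young TCR were then followed in the aged TRM library, with young TCR as the common reference. Of the 484 genes that rose in young TRM, 270 (55.8%) stood at least 2-fold above young TCR in aged TRM, and 353 (72.9%) lay between the young libraries. Of the 417 that fell, 180 (43.2%) stood at least 2-fold below young TCR and 324 (77.7%) lay between. Itgae at 320 CPM, Ldlrad4 at 238 CPM, Pmepa1 at 125 CPM and Ahr at 48.7 CPM stayed far above young TCR, with a log2 ratio of 5.01 for Itgae. Ifit3 at 12.1 CPM lay far below young TRM but above its 4.81 CPM in young TCR (log2 ratio 1.17), and Foxp3 had 3.71 CPM against 1.95 CPM in young TCR (0.68). By list, the median against young TCR was 1.05 for tissue residency genes, 1.19 for TGF-beta response genes, -0.02 for interferon response genes and 0.46 for cytotoxic granule genes. Altogether 482 genes were higher and 272 lower in aged TRM than in young TCR, of 11688 tested. Age and the added cytokines both differed between these libraries.

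Among 11386 genes tested in both comparisons, 484 rose and 357 fell in young TRM against young TCR. Of those that rose, 70 fell in aged TRM against young TRM and 18 rose again. Of those that fell, 99 rose in aged TRM against young TRM and 1 fell again. Independent lists of these sizes would share 5.65, 9.27, 6.84 and 4.17 genes in the same order, but these comparisons are not independent. A gene under 1 CPM in young TRM also cannot be called lower again with a pseudocount of 1. The count of 1 that fell again is thus partly set by the rule. The young TRM library enters both comparisons, which by itself sets their log2 ratios against each other. Across genes the log2 ratios of both comparisons had a Pearson r of -0.477, and data simulated with counting error as the only difference between libraries gave -0.517, but the covariance was -0.119 in the data and -0.00356 in the simulation. With a different column of the same library in each comparison, r was -0.427 or -0.449, and the opposite overlaps were 66 and 97 genes or 71 and 111 genes. Counting error alone was thus too small to give the covariance, while a difference of the whole young TRM sample would enter both comparisons and was not tested.

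**Figure D3:**
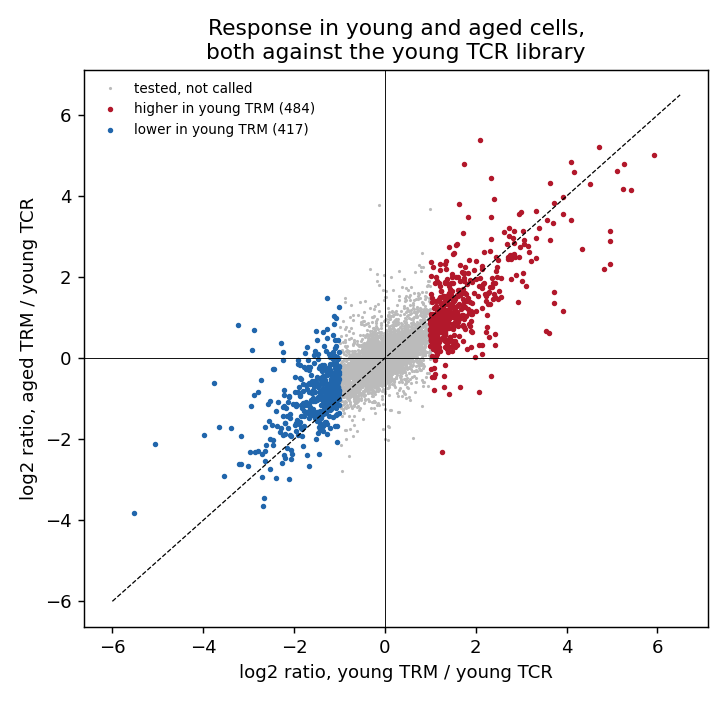
Log2 ratio of each tested gene in young TRM over young TCR (horizontal axis) and in aged TRM over young TCR (vertical axis), with the 484 genes that rose in young TRM in red, the 417 that fell in blue and the diagonal dashed. Of the red genes 72.9% and of the blue genes 77.7% lie between 0 and the diagonal.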

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

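The settings with 1 column alone, with all 4 column pairings or with a column for selection and the other for measurement were chosen after the data were seen, and the others beforehand. Counts of called genes moved by over 1.5 times under these settings, as follows from each setting's own construction. With a pseudocount of 5, which shrinks ratios of weakly expressed genes, 296 genes were higher and 190 lower in young TRM than in young TCR, and 87 were higher and 62 lower in aged than in young TRM. With a pseudocount of 0.25, 426 genes were higher in aged TRM. With genes of at least 10 CPM alone, 234 were lower in young TRM and 123 higher in aged TRM. At a threshold of 1.5-fold the first comparison gave 1091 higher and 1054 lower genes and the age comparison 731 and 445. At 4-fold the counts were 115 and 76, and 37 and 19. With the authors' TPM, 5 gene lists lay below matched lists in young TRM, against 8, and the cause was not tested. The other 86 recomputed counts and shares stayed within 1.5 times, among them 441 and 448 genes in the first comparison and 280 and 123 in the age comparison with scaling by totals only. No called result turned its direction under the settings tried. Of 519 recomputed list medians 486 kept their side of the limits, 20 fell inside and 13 moved out, and of 2037 recomputed log2 ratios of named genes 1929 kept their side, 71 no longer passed, 46 of them with a pseudocount of 5, and 37 passed anew. Thinned to equal depth, which left between 36021785 and 36025487 reads per library and so removed few, the counts were 484 and 417, and 253 and 130. What depth limits was not tested beyond that. Differences between mice cannot be estimated at any depth with 1 library per group.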

Other observations

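The tests of explanations in this part were all chosen after the result was seen, as were the genes named here, the shares of response kept by list and the counts of genes beyond both young libraries. The aged TRM library was not only placed between the young libraries. In it 107 genes were higher than in both young libraries by the calling rule and 26 were lower than in both. Ifng stood at 478 CPM against 103 in young TCR and 82.1 in young TRM, Gzmc at 413 against 31.5 and 63.5, Ccl3 at 131 against 34.4 and 30.6, and Il1a, an alarmin gene, at 33.6 against 0.247 and 3.18. Spp1, which encodes osteopontin, had 146 CPM in aged TRM against 54.8 and 37.3. Gpr15, a homing receptor of the large intestine, had 30.6 CPM against 0.444 and 6.27, so that it was higher in young TRM than in young TCR and higher again in aged TRM. On the lower side S1pr1 had 14.5 CPM against 51.4 and 50.2, and St6gal1, a sialyltransferase gene, 10.3 against 44.3 and 44.6.

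A further 70 genes were higher in young TRM than in both other libraries and 99 were lower in young TRM than in both others. The metallothionein genes Mt1 and Mt2, which bind zinc, had 50.1 and 29.1 CPM in young TCR, 9.82 and 5.17 CPM in young TRM, and 55.9 and 38.0 CPM in aged TRM. Interleukin 18 receptor transcripts were higher in both TRM libraries than in young TCR. In the same order, Il18r1 had 10.7, 80.7 and 67.6 CPM and Il18rap 19.5, 55.6 and 48.5 CPM. So was the activin receptor gene Acvr2a higher, at 3.75, 33.1 and 32.9 CPM. For genes called in the first comparison, the share of the young log2 ratio that aged TRM kept over young TCR was taken by list. The median was 90.1% over 13 tissue residency genes, 89.6% over 10 NK receptor genes and 85.2% over 12 TGF-beta response genes. It was 47.5% over 8 cytotoxic granule genes, 42.9% over 18 interferon response genes and 20.0% over 4 apoptosis regulators. Single genes differed widely, with shares from -0.14 to 1.15 among TGF-beta response genes. The tissue residency and TGF-beta lists share Itgae, Ldlrad4 and Skil. Most of the called NK receptor genes lost their call with a pseudocount of 5.

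Interferon response genes as a list were above young TCR in young TRM and below young TRM in aged TRM. Some stayed well above young TCR in aged TRM, with Isg20 at 28.8 against 3.58 CPM and Iigp1 at 528 against 134 CPM, and the 18 genes called in the first comparison kept a median of 42.9% of their log2 ratio. An error in a single deposited column as the cause is argued against, since the smallest size of the list's median over both comparisons with either column alone was 0.83. A young TRM library that stands out for a reason other than the cytokines cannot be told apart from a weaker interferon response in aged cells. The list's median in aged TRM against young TCR was -0.023 (bootstrap interval over genes -0.42 to 0.47), over members that went both ways, which decides nothing, and there is no other young TRM library. Age itself remains open and untested.

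Genes called in young TRM against young TCR mostly lay nearer to young TCR in aged TRM. Selection of genes on noise between reads or columns is argued against as the whole cause, since with selection on 1 column and measurement on the other at least 70.1% still lay between the young libraries. A uniformly weaker response from the same starting levels as young TCR is argued against for the TGF-beta and interferon lists in these libraries. TGF-beta response genes kept 0.42 more of their log2 ratio, as a share, than interferon response genes did (bootstrap interval over genes 0.24 to 0.59). That interval covers the spread between genes only, not between cultures or mice. If aged cells started from other levels, a uniformly weaker response may also give unequal shares. That cannot be told, since an aged sample with receptor stimulation alone was not analysed here. A young TRM sample that differs from other young cultures in part of its genes may give the same pattern, and so may age. With 1 library per group neither was tested.

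Granule and cytokine genes were higher in aged than in young TRM. Whether more NK cells in the aged culture contribute cannot be told. The NK and innate lymphoid markers had a median log2 ratio of 0.12 (bootstrap interval over genes -0.20 to 0.55), below the granule median of 1.2, but 9 of 10 had under 10 CPM in both libraries. The NK receptor genes lay above matched genes at 0.44, and at 0.96 with genes of at least 10 CPM. A larger share of antigen-experienced cells in the aged isolate may contribute, with naive and stem-like memory genes at -0.25 (bootstrap interval over genes -0.53 to -0.07). That share cannot be told apart from a change within each cell, since bulk RNA gives the same values for both.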
